A study of Rattus norvegicus with 144 samples.

How the data were processed

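Blood RNA of 72 male F344/N rats was measured on 144 2-colour oligonucleotide arrays, 2 per animal with the dyes exchanged, each against a pool of vehicle RNA of the same time. Doses of 0, 150, 1500 and 2000 mg/kg and times of 3, 6 and 24 h form 12 groups of 6 animals. Time and dye orientation were read from the sample labels. Dose was read from a deposited key that lists each animal number, and 72 of 72 times in the key matched the labels. In the key 19 animal numbers had lost zeros at their ends, and they were matched on the remaining digits, which are unique.

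The deposited values are taken as log10 ratios of Cy5 over Cy3 that the authors had already dye-normalised; the scale, the centring and the direction are not given in the sources used here. The number format is that of a scanner's log ratio column, so a log10 scale and Cy5 over Cy3 are likely and not certain. The medians of the nonzero values per array lay between -0.00821 and 0.00865 and their SDs between 0.0993 and 0.269, with extremes of -3.31 and 2.95. Of all values 10.8% were exactly 0 (2.33 to 18.4% per array), and these were treated as missing. The table holds 22075 features, of which 500 are absent on 91 arrays and were not used, which left 21575. Arrays that lack the 500 features are called 1 array design and the others the second design.

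Values were turned to log2 of animal over pool by changing the sign where the animal was in Cy3. After the mean of each dye orientation was taken off, the 2 arrays of an animal correlated negatively in 53 of 72 animals (median -0.168, lowest -0.553, highest 0.287), as a ratio that follows the dyes would give, while 19 animals did not show it. Only for 11 of 72 animals was the own turned Cy3 array the one that correlated best with the Cy5 array. By dose the medians were -0.056, -0.0517, -0.169 and -0.344. The dye effect common to arrays had an SD of 0.34 on the log2 scale and cancels in the mean of the 2 arrays. An animal's value is the mean of its 2 arrays, and both were needed. Probes with 1 symbol (12750) were averaged per gene, giving 9653 genes of which 2266 had more than 1 probe; probes with several symbols (5) or none (9320) were kept singly, and control probes could not be told apart among them. Symbols were matched to a rat gene table (12720 probes matched, 0 symbols updated). A feature needed a value in 4 of 6 animals in each group, which left 14678 features, 8354 named genes and 6324 unnamed probes, with 0.687% of animal values missing. No value was imputed for the test of single features.

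Differences were tested with limma 3.58.1 in R 4.3.3, in 1 fit of 12 group means over all 72 animals (prior degrees of freedom 2.37), with Benjamini-Hochberg adjustment over the features of a comparison and a threshold of 0.05, two-sided. Comparisons were each dose against 0 mg/kg, 2000 against 1500 and 1500 against 150 mg/kg at each time, and the change of the 2000 mg/kg difference between times. Genes were named by a rule: for 2000 mg/kg the 10 largest rises and 10 largest falls among named genes past the threshold with every animal on the same side of the vehicle mean, for 1500 and 150 mg/kg the 5 and 5 by the same rule, and without a condition on single animals the 3 and 3 for the differences between times and up to 4 members past the threshold per list.

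Gene lists, 24 with at least 5 measured members, were written from general knowledge: T cell, B cell, natural killer, monocyte, neutrophil, platelet and erythroid markers, ribosomal proteins, oxidative phosphorylation, interferon, inflammatory, immediate early, NRF2 and glutathione, heat shock, unfolded protein, hypoxia and glycolysis, p53 and apoptosis, cell cycle, circadian, fatty acid oxidation, glucocorticoid, metallothionein, liver-secreted and cell adhesion genes. Overlap is small: 3 glucocorticoid genes and 1 each of the circadian, fatty acid and immediate early genes are also in another list. They were tested with limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation, with missing values filled by group means. The mean over a list's members per animal was compared by an exact permutation test, two-sided, over 924 groupings of 6 against 6, whose smallest p is 0.00216. Statmod 1.5.0 served the random block. Animals were assigned to a dose by leaving 1 animal out and taking the nearest group mean over the 100 features with the largest F among the other animals. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

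The groups, comparisons, lists, naming rule, threshold and most alternatives were chosen before the data were examined. Chosen after seeing the data were the exact test of list scores, the treatment of exact zeros and of single arrays, the array design as a covariate or restriction, the split of controls for 150 and 2000 mg/kg and the fit without animals apart within their group. Other alternatives were centring or scaling of arrays, 1 dye orientation, a fit per time, single arrays with the animal as a random block, robust empirical Bayes, array weights, single probes, other filters, a 1.5-fold minimum, the pool as control and leaving out each animal. Recovery of planted changes was tested on simulated data. No paired analysis was possible because each animal was sampled at 1 time and dose.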

Results

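Gene expression was measured in the blood of 72 male F344/N rats given acetaminophen, an analgesic that injures the liver in overdose. Rats received 0 (vehicle), 150, 1500 or 2000 mg/kg by gavage, and blood was taken 3, 6 or 24 h later, with 6 rats in each of the 12 groups. Each rat was hybridised on 2 arrays with the dyes exchanged, against RNA pooled from the vehicle animals of the same time, which gave 144 arrays. The animals formed a blinded set whose doses stood in a separate key, so the design asks which transcripts moved with dose and whether a blood profile places an animal in its dose group. For each of 14678 features, 8354 of them named genes, the mean log2 ratio of a dose group was set against that of the 6 individual vehicle animals of the same time. The number of animals and arrays limits the precision of each difference, which is given with its standard error (SE). The number of animals showing a direction is counted against the mean of the vehicle animals. The genes with the largest rises and falls against vehicle were named only if every animal with a value lay on that side. For them a count such as 6 of 6 was fixed by this choice and is no further support. The log base and the direction of the deposited ratios are not stated and were taken as likely from the number format. Every "higher" and "lower", and the size of every fold, log2 difference and SE, rests on that reading.

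The lowest dose gave no change that passed the test at any time. With limma, 0 of 14678 features differed between 150 and 0 mg/kg at 3, 6 or 24 h, while 616, 693 and 399 features had an unadjusted p under 0.05, where chance alone gives 734. In simulated data of the same size, 62.7% (3 h), 82.1% (6 h) and 70.1% (24 h) of genes changed 1.5-fold were called, and 98.5%, 98.5% and 97% of those changed 2-fold. Each simulation was 1 draw with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold together, and errors independent between genes. The larger changes ease the adjusted threshold, so these shares may overstate the recovery of a few small changes. The spread was shared by all 12 groups, and for some genes the higher doses widened it. For Il1r2 at 6 h the SD was 0.16 at 0, 0.28 at 150 and 0.94 at 1500 mg/kg, and the SE 0.37. Changes at 150 mg/kg in such genes may be missed. The simulation drew on the same shared spread and cannot show this. No member of any gene list passed. With camera at a preset correlation the oxidative phosphorylation (adjusted p = 6.42e-05), ribosomal protein (adjusted p = 0.0169) and heat shock (adjusted p = 0.0288) lists were higher at 3 h, and the erythroid list at 6 h (adjusted p = 0.0463). None passed with an estimated correlation (adjusted p = 0.33, 0.735, 0.203 and 0.609), and the exact permutation p of the mean list score, two-sided, was 0.158, 0.5, 0.0411 and 0.0714 (0.646, 0.831, 0.584 and 0.429 adjusted over the lists). With the array design as a covariate, camera at the preset correlation still passed the oxidative phosphorylation (adjusted p = 1.91e-06) and ribosomal lists (adjusted p = 0.00119) but not the heat shock (adjusted p = 0.0599) or erythroid list (adjusted p = 0.246). Within 1 design (5 treated, 2 vehicle animals) the means of the first pair were 0.20 and 0.26, against 0.10 and 0.08 over all animals. Without treated animal 0460, which also lay over 2 SD from the centre on a component within groups, the 2 means were 0.06 and 0.00. The oxidative phosphorylation mean was 0.14 without treated animal 2222, and the ribosomal mean 0.13 without treated animal 7532. Other settings called few features: 8 at 6 h with array weights, and 2 at 3 h and 3 at 6 h among animals with arrays of 1 design. Against the pool in place of the individual controls, the counts were 8, 28 and 104.

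**Figure D1:**
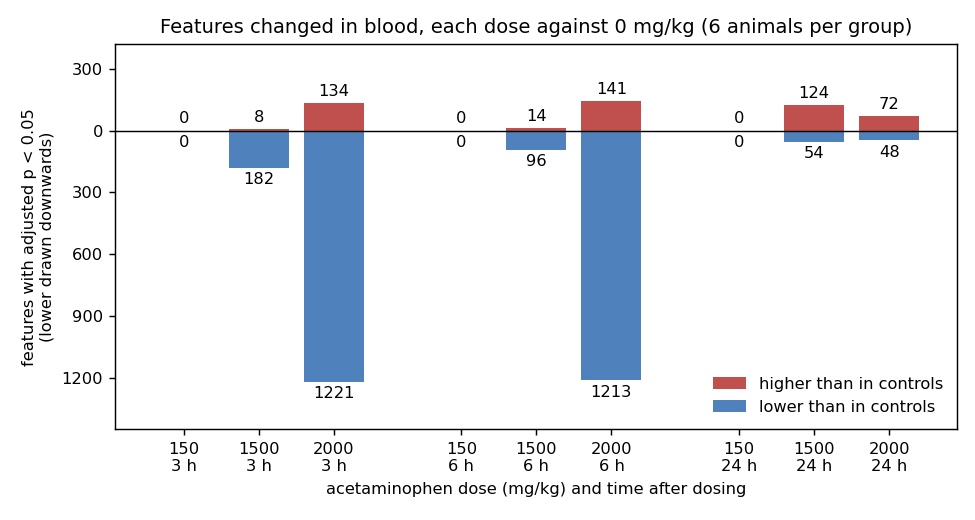
Number of features (y axis) higher (upward bars) or lower (downward bars) than in vehicle animals at each dose (mg/kg) and time (both along 1 x axis), with 6 animals per group and an adjusted p under 0.05. The bars for lower features are the longer ones at 3 and 6 h, those for higher features at 24 h, and 150 mg/kg has none.

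At 3 h after 2000 mg/kg most changed features were lower than in vehicle animals, and the 10 named genes with the largest falls were 3.34-fold to 3.98-fold lower. Jchain, the joining chain of polymeric immunoglobulins, fell 3.98-fold (log2 difference -1.99, SE 0.34, adjusted p = 4.65e-05, lower in 5 of 5 animals with a value). C5ar1, the receptor for the complement fragment C5a, fell 3.96-fold (-1.99, SE 0.26, adjusted p = 6.85e-07, 6 of 6 animals). Ifi30, a lysosomal thiol reductase of antigen processing, fell 3.92-fold (-1.97, SE 0.29, adjusted p = 4.54e-06, 6 of 6), and Fn1, which encodes fibronectin, fell 3.79-fold (-1.92, SE 0.27, adjusted p = 2.9e-06, 6 of 6). Mnda, a nuclear protein of myeloid cells, Spib, a transcription factor of B cells, Bcl2a1, an inhibitor of apoptosis, Hnrnpa2b1, Bin1 and Coro1a, an actin-binding protein of leukocytes, had log2 differences from -1.85 to -1.74 and were lower in every animal with a value. Rises were fewer. The largest was in Rbp7, a cellular retinol-binding protein, which rose 4.84-fold (2.28, SE 0.76, adjusted p = 0.0481, 5 of 5 animals with a value). Ndrg4, Gjb6 (a gap junction protein), Madd, Klk12, Bpifa2f, Tcam1, Selp (P-selectin, of platelets and endothelium), Elk4 and Zfp346 rose 1.52-fold to 1.81-fold, higher in 6 of 6 animals, although 1 animal lay far above the other 5 for Gjb6, Madd and Bpifa2f. In all, 1355 features changed, 134 higher and 1221 lower, and 3039 had an unadjusted p under 0.05. Without vehicle animal 6370 the count was 872, with array weights 3917 (1458 higher), and against the pool 4588.

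At 3 h after 2000 mg/kg part of the T cell, B cell, ribosomal and oxidative phosphorylation lists fell. Of 14 T cell markers 6 fell and none rose, among them Cd5 (-1.69), Cd6 (-1.34), Lck (-1.34) and Zap70 (-1.17), the last pair being kinases of the T cell receptor. Of 10 B cell markers 4 fell, Jchain and Spib with Blnk (-1.29), an adaptor of the B cell receptor, and Ms4a1 (-0.91), which encodes CD20 and whose probes parted (-1.97 and 0.16). Of 51 ribosomal protein genes 26 fell, led by Rpl6 (-1.21), Rpl5 (-1.19), Rpl27 (-1.15) and Rpl8 (-1.13), and of 58 oxidative phosphorylation genes 20 fell, including the ATP synthase subunits Atp5f1c (-1.22), Atp5f1a (-1.06) and Atp5f1e (-1.03) and Sdha (-1.16) of complex II. Adjusted over the list alone, 6, 5, 38 and 22 members fell. The list medians were -0.53 (T cell), -0.26 (B cell), -0.46 (ribosomal) and -0.18 (oxidative phosphorylation). Camera placed all 4 lists below the other genes (adjusted p = 3.78e-05, 6.88e-05, 3.56e-20 and 8.28e-09), but none held with correlations estimated from the data (adjusted p = 0.141, 0.116, 0.116 and 0.116 with an estimated correlation). In each of the 4 lists all 6 treated animals scored below all 6 vehicle animals, which gives an exact two-sided permutation p of 0.00216, the smallest that 6 against 6 can give (0.00866 adjusted over the lists). The interferon list (5 of 25 fell, also 5 adjusted over the list alone) had a median of -0.08 and adjusted p = 0.0114, lost at adjusted p = 0.544 with an estimated correlation. Ifi27l2b (-1.67), the immunoproteasome subunit Psmb8 (-1.25), the kinase Eif2ak2 (-0.99) and Bst2 (-0.65) fell in it, and its exact p was 0.00433. Of 26 immediate early genes 7 fell (10 adjusted over the list alone, and 1 rose), among them the phosphatase Dusp6 (-1.64), the nuclear receptor Nr4a1 (-1.12), Rgs2 (-1.11) and Klf6 (-1.01), with a list mean of -0.26 and adjusted p = 0.0358, lost at adjusted p = 0.116 with an estimated correlation.

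The other 18 lists did not pass camera at 3 h after 2000 mg/kg. Members that fell were Lyz2 (lysozyme, -1.69), Fcgr1a (-0.92), Tyrobp (-0.57) and Lgals3 (-0.47) of 16 monocyte and macrophage markers, of which 4 fell and 2 rose (3 rose and 4 fell adjusted over the list alone). Of 15 neutrophil markers 3 fell, Ncf4 (-1.07), Anxa1 (-0.95) and Cyba (-0.72), and 3 also adjusted over the list alone. Of 36 inflammatory genes 4 fell, among them Il1b (interleukin 1 beta, -1.37) and Nfkbia (-0.75). Of 32 NRF2 and glutathione genes 4 fell, with the regulator Nfe2l2 itself at -1.08 and Tkt, of the pentose phosphate pathway, at -0.94. Of 29 hypoxia and glycolysis genes 4 fell, including Pgk1 (-0.92), and of 25 p53 and apoptosis genes 2 fell, Bcl2a1 (-1.76) and Casp1 (-1.22). The heat shock list (21 members) had 2 falls, Hsp90aa1 (-0.87) and Hspe1 (-0.42). 1 member each fell in the natural killer (16 members, Klrd1 -0.59), unfolded protein (24, Pdia4 -0.76), cell adhesion (10, Fn1), cell cycle (28, Mcm4 -0.64) and circadian (12, Dbp -0.23) lists. Of 31 liver-secreted transcripts C3 fell (-0.75) and A2m rose (0.20), of 16 glucocorticoid targets Fkbp5 rose (0.39) and Il6r fell (-0.84), and of 12 platelet genes Selp rose (0.70). No member passed in the erythroid (27 members), fatty acid oxidation (25) or metallothionein (5) lists. Their adjusted p values by camera, in the order natural killer, erythroid, neutrophil and unfolded protein, were 0.149 each, and the rest lay between 0.215 and 0.856. The median and the mean had opposite signs in the monocyte, inflammatory, hypoxia, p53, cell adhesion, cell cycle, glucocorticoid and fatty acid lists.

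Arrays came in 2 designs, of which 1 lacks 500 features, and the designs were spread unevenly over the groups at 3 and 6 h. The vehicle and 2000 mg/kg groups at 6 h were alike, with 10 of 12 arrays lacking the 500 features in each. With the design as a covariate 1392 features changed at 3 h after 2000 mg/kg, 1258 lower, and the means of the T cell, B cell, ribosomal and oxidative phosphorylation lists were -0.60, -0.64, -0.49 and -0.30. Among animals with both arrays of the fuller design (4 treated, 2 vehicle) 1 feature passed, but 1232 of 1234 changed features kept their sign, at a median size of 0.515 against 0.676, and the list means were -0.59, -0.48, -0.36 and -0.20. The animals of 1 design are part of those from which the changed features were chosen. A kept sign was therefore likely, here and in the counts of kept signs below.

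At 3 h after 1500 mg/kg fewer features passed, again mostly lower. Fn1 fell 3.11-fold (-1.64, SE 0.27, adjusted p = 0.000832, 6 of 6 animals), Fcnb, a ficolin that binds microbial sugars, 3.03-fold (-1.60, SE 0.35, adjusted p = 0.0135, 6 of 6), and Ifi30 2.82-fold (-1.50, SE 0.29, adjusted p = 0.00672, 6 of 6). Spib (-1.43) and C5ar1 (-1.23) also fell in 6 of 6 animals. Gjb6 (0.81), Cenpu, a centromere protein (0.39), Sync (0.39) and St8sia3, a sialyltransferase (0.23), rose in 6 of 6, although for St8sia3 vehicle animal 7558 lay far below the other vehicle animals. Of the B cell markers 3 of 10 fell (5 adjusted over the list alone), Spib with Blnk (-1.05) and Ms4a1 (-0.64, with its probes at -1.33 and 0.04), and the list had a median of -0.29 and adjusted p = 1.71e-05, not held at adjusted p = 0.114 with an estimated correlation. Of the ribosomal genes 4 of 51 fell (27 over the list alone), Rpl27 (-0.84), Rps13 (-0.77), Rpl36 (-0.58) and Rpl32 (-0.43), with a median of -0.33 and adjusted p = 1.96e-15, not held at adjusted p = 0.167 with an estimated correlation. Of the oxidative phosphorylation genes 3 of 58 fell (13 over the list alone), Atp5f1c (-0.79), Atp5f1e (-0.78) and Atp5mc3 (-0.62), with a median of -0.08 and adjusted p = 0.000407, not held at adjusted p = 0.478 with an estimated correlation. No T cell marker passed over all genes, while 6 fell and 1 rose adjusted over the list alone; the list median was -0.38 and adjusted p = 0.000453, not held at adjusted p = 0.342 with an estimated correlation. These 4 lists each had an exact two-sided permutation p of 0.00216, with all 6 animals below all vehicle animals. The erythroid list was higher (median 0.11, 0 of 27 members past, adjusted p = 8.85e-05), not held at adjusted p = 0.114 with an estimated correlation, with an exact p of 0.0195. Within 1 array design (4 treated, 2 vehicle animals) the list means shrank from -0.34 to -0.16 (ribosomal), -0.50 to -0.29 (B cell), -0.17 to -0.10 (oxidative phosphorylation) and 0.13 to 0.07 (erythroid), while the T cell mean was -0.39 in both. In all 190 features changed, 8 higher and 182 lower (1940 with an unadjusted p under 0.05). The count was 10 without vehicle animal 6370, 33 without vehicle animal 8282, 36 without vehicle animal 8691, and 14, 44, 71 and 119 without treated animals 1286, 4258, 5027 and 6622. It was 297 with the array design as a covariate, 1 within 1 design, where 182 of 182 changed features kept their sign at a median size of 0.545 against 0.787, 1214 with array weights and 651 on single arrays with the animal as a random block.

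**Figure D2:**
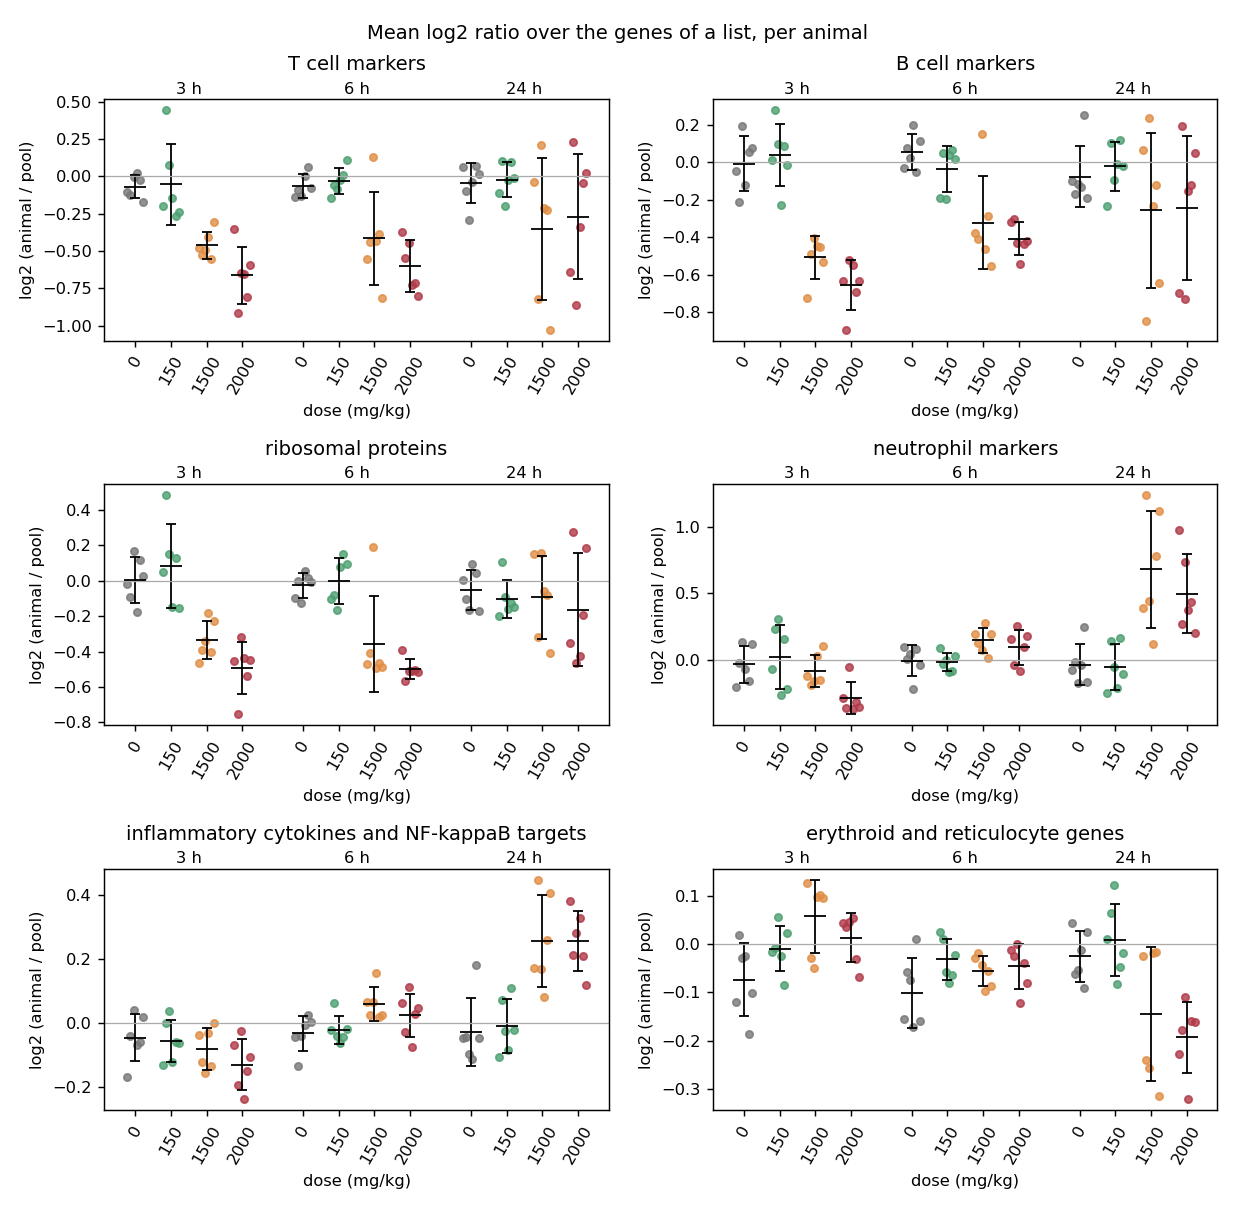
Mean log2 ratio over the members of 6 gene lists (y axis) for each animal (points) by time and dose (x axis), with the group mean as a bar and the SD of 6 animals as an error bar. T cell, B cell and ribosomal scores lie below the vehicle animals at 1500 and 2000 mg/kg at 3 h, and neutrophil and inflammatory scores lie above most of them at 24 h.

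At 6 h after 2000 mg/kg most changed features were again lower, and a decoy receptor of interleukin 1 was among those that rose. Il1r2, which binds interleukin 1 without signalling, rose 4-fold (SE 0.37 on the log2 scale, adjusted p = 0.000665, 6 of 6 animals). At 3 h Il1r2 had been above the highest vehicle animal in every animal at 1500 mg/kg (0.99, adjusted p = 0.16) and 2000 mg/kg (0.70, adjusted p = 0.27) without passing, and its difference between 6 and 3 h did not pass. Serpinb1a, an inhibitor of neutrophil proteases, rose 2.47-fold (1.30, SE 0.42, adjusted p = 0.0348, 6 of 6). Adck1, Tas2r110, Dcbld2, Si, Fbxo39, Cpxm1, Cpne8 and Bphl rose by 0.50 to 0.71 in every animal with a value, but 1 of 3 probes for Bphl had the other sign, and for Cpne8 1 animal lay far above the rest. Ramp1, a receptor activity modifier, fell 3.05-fold (-1.61, SE 0.32, adjusted p = 0.00127, 6 of 6), Crip1, a zinc-binding LIM protein, 3.01-fold (-1.59, SE 0.28, adjusted p = 0.000615, 6 of 6), Myof 2.98-fold (-1.58, SE 0.25, adjusted p = 0.000141, 6 of 6) and S100a10, a partner of annexin A2, 2.93-fold (-1.55, SE 0.23, adjusted p = 6.21e-05, 6 of 6), where vehicle animal 6034 lay below the other vehicle animals. Abi3, Dusp22, Tcp1 (a chaperonin subunit), Mnda, Bcl2a1 and Jchain fell by 1.5 to 1.45 on the log2 scale in 6 of 6 animals. Altogether 1354 features changed, 141 higher and 1213 lower (3244 with an unadjusted p under 0.05). The count was 1378 with the array design as a covariate and 1556 within 1 design (5 against 5 animals), where 1246 of 1246 changed features kept their sign. It was 3466 with array weights (1056 higher), 738 with a change of at least 1.5-fold and 5655 against the pool.

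At 6 h after 2000 mg/kg 4 lists passed camera as lower, the T cell, B cell, ribosomal and oxidative phosphorylation lists. The interferon (2 of 25 fell, adjusted p = 0.808) and immediate early lists (2 of 26 rose and 2 fell, adjusted p = 0.962), which were lower at 3 h with the preset correlation only, did not pass. Of 14 T cell markers 6 fell (7 adjusted over the list alone), with Cd5 at -1.20, Lck at -1.19, Cd6 at -1.12 and Zap70 at -1.11. Of 10 B cell markers 5 fell (5 over the list alone), among them Jchain (-1.45), Spib (-1.27), Blnk (-0.86) and Ms4a1 (-0.64, with its probes at -1.42 and 0.13). Of 51 ribosomal genes 24 fell (34 over the list alone), led by Rpl5 (-1.17), Rpl8 (-1.09), Rps6 (-1.09) and Rpl6 (-1.05), and of 58 oxidative phosphorylation genes 20 fell (27 over the list alone), led by Atp5f1c (-1.18) and Atp5f1a (-0.95). The medians were -0.58, -0.22, -0.38 and -0.26, with camera adjusted p = 0.000398, 0.012, 2.36e-17 and 3.4e-09. None held with correlations estimated from the data (adjusted p = 0.421, 0.492, 0.202 and 0.202 with an estimated correlation), and in each the 6 treated animals lay below all 6 vehicle animals (exact two-sided permutation p = 0.00216, adjusted 0.0104). Within 1 array design the list means were -0.60, -0.50, -0.51 and -0.33, against -0.54, -0.46, -0.47 and -0.31 over all animals. The neutrophil list was not lower (median 0.07, 1 of 15 fell, adjusted p = 0.44). Among other lists that did not pass, Herpud1 (-1.19) and Edem1 (-1.15) of the unfolded protein response fell, as did Pcna (-0.73) and Mcm5 (-0.61), which act in DNA replication, Acadm (-0.44) and Acads (-0.44) of fatty acid oxidation, and Mt1, a metallothionein (-0.49). Pdk4 (0.30), Dusp1 (0.27) and Egr3 (0.18) rose.

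At 6 h after 1500 mg/kg Il1r2 rose 3.59-fold (1.84, SE 0.37, adjusted p = 0.0237, higher in 6 of 6 animals). Ankrd34b (0.61, with 1 animal far above the rest), Aqp11, an aquaporin (0.47), and the immediate early genes Dusp1 (0.28) and Egr3 (0.21) rose in 6 of 6. Crip1 fell 2.45-fold (-1.29, SE 0.28, adjusted p = 0.0263), Jchain 2.43-fold (-1.28, SE 0.32, adjusted p = 0.0472), Skic8 2.4-fold (-1.27, SE 0.27, adjusted p = 0.0263) and Tcp1 2.31-fold (-1.21, SE 0.24, adjusted p = 0.0237), each in 6 of 6 animals, and Sumo2 fell by 0.97, with animal 0621 far above the rest. Of 51 ribosomal genes 2 fell, Rps13 (-0.83) and Rpl36 (-0.58), and 22 fell adjusted over the list alone. Of 58 oxidative phosphorylation genes 4 fell (14 over the list alone), among them Atp5f1c (-0.84) and Uqcrc2 (-0.71). Of the B cell markers 1 of 10 fell (4 over the list alone) and of the T cell markers 0 of 14 (4 over the list alone). The ribosomal, oxidative phosphorylation, B cell and T cell lists had medians of -0.31, -0.16, -0.11 and -0.35 and camera adjusted p = 1.3e-12, 5.99e-07, 0.00132 and 0.00413. None held (adjusted p = 0.273, 0.273, 0.273 and 0.413 with an estimated correlation), and the exact two-sided permutation p, from 0.013 to 0.0238, did not pass once adjusted over the lists. Within 1 array design (2 treated, 5 vehicle animals) the list means were -0.47, -0.25, -0.49 and -0.55, against -0.33, -0.21, -0.38 and -0.35 over all animals, and 766 features changed. The treated animals kept there were 4178 and 9676, so animal 0621 was left out too, and its part in the gain cannot be told apart. Animal 0621 of this group scored 0.13 for T cell markers and 0.19 for ribosomal proteins, above every vehicle animal, and its Il1r2 value was 0.03. In all 110 features changed, 14 higher and 96 lower (2141 with an unadjusted p under 0.05). The count rose to 993 without animal 0621 and was 0 without treated animal 0426 or 9676 or vehicle animal 3273 or 6749. It was 3 without 0089, 6 without 4178, and 7, 10, 9 and 48 without vehicle animals 4101, 6034, 7270 and 9709.

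**Figure D3:**
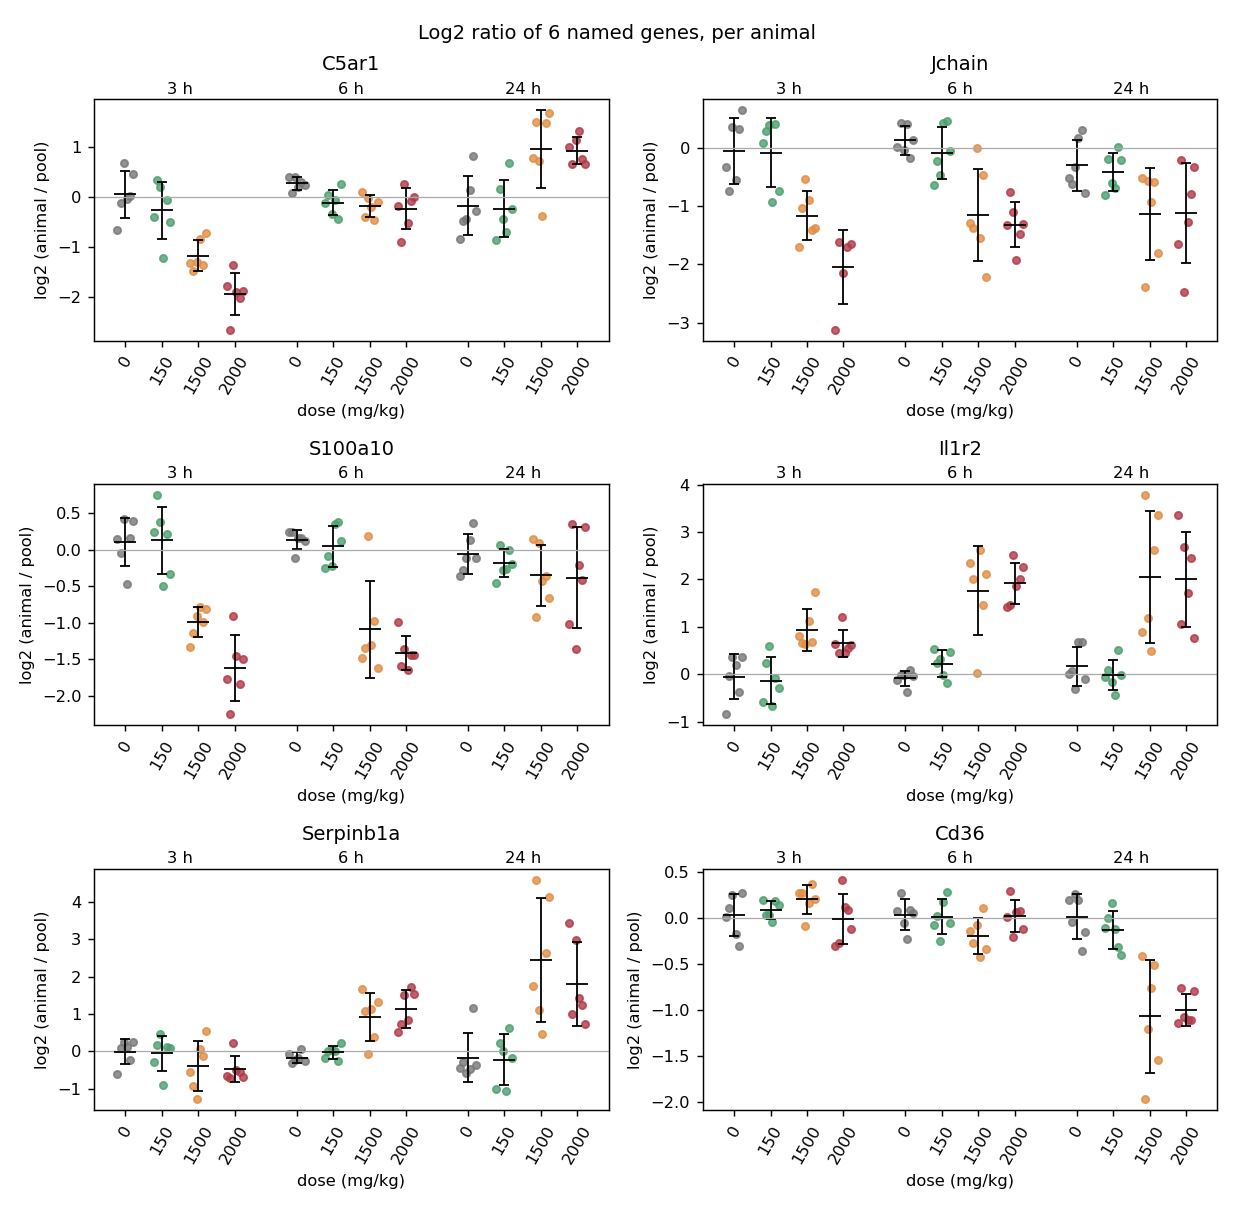
Log2 ratio of each animal against the pool (y axis) for 6 genes by time and dose (x axis), with points for animals, a bar for the mean and an error bar for the SD. C5ar1 lies lowest at 3 h after 2000 mg/kg (mean -1.94, SD 0.42, n = 6) and is above the vehicle mean at 24 h (0.92, SD 0.27, n = 6), and Cd36 is low only in the 1500 and 2000 mg/kg groups at 24 h.

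At 24 h after 2000 mg/kg the pattern differed, and genes of neutrophils and inflammation were higher. Serpinb1a rose 3.91-fold (1.97, SE 0.42, adjusted p = 0.00611, 6 of 6 animals), Il1r2 3.57-fold (1.84, SE 0.37, adjusted p = 0.00447, 6 of 6), S100a9, a calprotectin subunit, 3.34-fold (1.74, SE 0.42, adjusted p = 0.022, 6 of 6) and Mmp8, neutrophil collagenase, 3.11-fold (1.64, SE 0.36, adjusted p = 0.00908, 6 of 6). Anxa1 (1.30), Cfd, complement factor D (1.28), Slpi, a leukocyte protease inhibitor (1.16), Il1b (1.10), C5ar1 (1.10) and Fcgr2b, an Fc receptor (1.10), rose in 6 of 6 animals. Cd36, a scavenger receptor and fatty acid transporter, fell 2.01-fold (-1.01, SE 0.15, adjusted p = 5.51e-05, 6 of 6), and Nrp1, Kpna1, Cir1, Cmas, Ranbp10, Enpp1, Gda, Usp15 and Bcas3 fell by 0.91 to 0.58 in 6 of 6. Vehicle animal 7067 lay far above the other vehicle animals for Serpinb1a, S100a9 and Slpi, as did 8002 for Cir1, and treated animal 5421 lay lowest for Gda. Of 15 neutrophil markers 4 rose and none fell (5 rose adjusted over the list alone), with a median of 0.14, adjusted p = 2.47e-05 and adjusted p = 0.0375 with an estimated correlation. Of 36 inflammatory genes 4 rose (6 over the list alone), Il1r2 and Il1b with Tlr2 (0.99), a receptor for bacterial lipoproteins, and Bcl3 (0.51), with a median of 0.13, adjusted p = 9.74e-06 and adjusted p = 0.00105 with an estimated correlation. Of 27 erythroid genes 2 fell (8 fell and 1 rose over the list alone), the mitophagy receptor Bnip3l (-0.58) and Blvrb (-0.30), with a median of -0.13, adjusted p = 9.74e-06 and adjusted p = 0.0357 with an estimated correlation. These 3 lists had exact two-sided permutation p = 0.00433, 0.00433 and 0.00216 (0.0346 each adjusted over the lists).

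The remaining lists that passed camera at 24 h after 2000 mg/kg lost the call. Fcgr1a (0.90) and Lgals3 (0.58) rose among the 16 monocyte markers (3 rose over the list alone; median 0.05, adjusted p = 0.0427, adjusted p = 0.0653 with an estimated correlation). Only Cd36 fell among 25 fatty acid oxidation genes (median -0.07, adjusted p = 0.0205, adjusted p = 0.07 with an estimated correlation). No member passed in the T cell, oxidative phosphorylation or ribosomal lists, with medians of -0.09, -0.07 and -0.11 and adjusted p = 0.00393, 0.0196 and 0.0196. None of these held (adjusted p = 0.306, 0.657 and 0.728 with an estimated correlation), and without animal 5402 their means went from -0.23, -0.08 and -0.11 to -0.11, -0.02 and -0.05. Without animal 2342 the means were -0.33, -0.13 and -0.20. Outside the lists that passed, Ccng1, a p53 target, rose (0.65) and Asns, asparagine synthetase, fell (-0.57). Altogether 120 features changed, 72 higher and 48 lower (1461 with an unadjusted p under 0.05). The count was 71 without animal 5421, 79 without vehicle animal 5480, 236 on single arrays with the animal as a random block, and 4 in a fit of the 24 h animals alone.

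At 24 h after 1500 mg/kg the same direction was seen. Serpinb1a rose 6.14-fold (2.62, SE 0.42, adjusted p = 0.000101, 6 of 6 animals), S100a9 5.54-fold (2.47, SE 0.42, adjusted p = 0.000199, 6 of 6), S100a8, the other calprotectin subunit, 3.98-fold (1.99, SE 0.43, adjusted p = 0.00411, 6 of 6), Mmp8 3.75-fold (1.91, SE 0.36, adjusted p = 0.000711, 6 of 6) and Il1r2 3.69-fold (1.88, SE 0.37, adjusted p = 0.00117, 6 of 6). Cd36 fell 2.12-fold (-1.08, SE 0.15, adjusted p = 7.87e-06, 6 of 6), Cmas, which activates sialic acid, by 0.85, Cat, catalase, by 0.80, Kpna1 by 0.79 and Ranbp10 by 0.76, each in 6 of 6 animals. Of 15 neutrophil markers 5 rose (6 over the list alone; median 0.23, adjusted p = 4.07e-10, adjusted p = 0.00094 with an estimated correlation). Of 36 inflammatory genes 4 rose (6 over the list alone), Il1r2, Tlr2 (1.19), Il1b (0.95) and Bcl3 (0.69), with a median of 0.06, adjusted p = 5.81e-06 and adjusted p = 0.00094 with an estimated correlation. Of 16 monocyte markers 3 rose (4 over the list alone), Fcgr1a (0.95), Lgals3 (0.61) and Tyrobp (0.45), with a median of 0.06, adjusted p = 0.00883 and adjusted p = 0.0115 with an estimated correlation. The exact two-sided permutation p of these 3 scores was 0.00433, 0.00866 and 0.00866, each 0.0649 once adjusted over the lists. The T cell (median -0.33, no member past, adjusted p = 0.000613) and erythroid lists (median -0.11, Bnip3l at -0.58, 6 fell and 1 rose over the list alone, adjusted p = 0.00234) were lower, and neither held (adjusted p = 0.201 and 0.143 with an estimated correlation). The T cell mean was -0.31, with -0.17 without animal 8385 and -0.42 without animal 2486. Tf, transferrin, rose by 1.44 (liver-secreted list), and Cebpd (1.08), Sgk1 (0.79) and Dusp1 (0.29) rose among 16 glucocorticoid targets, in lists that did not pass. In the NRF2 list Txnrd1 rose (0.60) and Cat and Gclm (-0.32) fell. In all 178 features changed, 124 higher and 54 lower (1348 with an unadjusted p under 0.05). The count was 101 without animal 0861, 115 without 8385, 272 without 3046, 90 with array weights and 40 in a fit of the 24 h animals alone. The treated animals varied widely, with an SD of 1.65 for Serpinb1a and 1.39 for Il1r2, against 0.66 and 0.41 in vehicle animals. The spread shared by all groups therefore understates the SE and p of these genes. At this time all but 1 array came from 1 design, and the counts with the design as a covariate were 180 (1500 mg/kg) and 124 (2000 mg/kg).

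Between 2000 and 1500 mg/kg no feature differed at 3, 6 or 24 h with limma (0 each, with 549, 677 and 506 at an unadjusted p under 0.05). With array weights 614 features differed at 3 h, 552 of them lower at 2000 mg/kg, and 614 at 6 h, 459 of them higher, so these counts rest on how animals are weighted. At 3 h the T cell list was lower at 2000 than at 1500 mg/kg (median -0.19, adjusted p = 0.0135, adjusted p = 0.422 with an estimated correlation), and so was the interferon list (median -0.09, adjusted p = 0.000232, adjusted p = 0.318 with an estimated correlation). Between 1500 and 150 mg/kg 481 features differed at 3 h (42 higher, 439 lower), 2 at 6 h and 152 at 24 h (100 higher, 52 lower). At 3 h Fcnb (-2.12, SE 0.35, adjusted p = 0.00032), Spib (-1.58, SE 0.35, adjusted p = 0.00884) and Fn1 (-1.50, SE 0.27, adjusted p = 0.00195) were lower at 1500 mg/kg. At 6 h the pair was S100a10 (-1.14, SE 0.23, adjusted p = 0.0329) and Padi2 (-0.68, SE 0.13, adjusted p = 0.0329), named after their values were seen, and Il1r2 did not pass (1.54, adjusted p = 0.107). At 24 h Serpinb1a (2.68, SE 0.42, adjusted p = 9.58e-05), S100a9 (2.59, SE 0.42, adjusted p = 0.000108) and Il1r2 (2.07, SE 0.37, adjusted p = 0.000344) were higher, and Cd36 was lower (-0.94, SE 0.15, adjusted p = 9.58e-05).

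The effect of 2000 mg/kg was compared between times by testing the difference of differences. From 3 to 6 h only St3gal4, a sialyltransferase, passed (1.43, SE 0.28, adjusted p = 0.0494; 626 features had an unadjusted p under 0.05, where chance gives 734). It did not pass with arrays centred (adjusted p = 0.0544), centred and scaled (adjusted p = 0.202), either dye orientation alone (adjusted p = 0.105 and 0.102) or robust empirical Bayes (adjusted p = 0.0517), but did with array weights. At 6 h, 4 of 6 treated animals lay above the vehicle mean for it, and the immediate early list was higher at 6 h (0 of 26 members past, 2 over the list alone; median 0.09, adjusted p = 0.00558, adjusted p = 0.0437 with an estimated correlation). From 6 to 24 h 538 features differed, 441 toward higher values, led by B4galnt4 (2.08, SE 0.41, adjusted p = 0.0016), Bcl2a1 (2.04, SE 0.33, adjusted p = 0.000152) and Frmd6 (1.98, SE 0.42, adjusted p = 0.00302), for which vehicle animal 5480 lay far below the others at 24 h. Gnat2 (-1.38), Tas2r110 (-1.0) and Cd36 (-1.0, SE 0.21, adjusted p = 0.00262) moved toward lower values. At 24 h only 4 of 6 treated animals lay on that side of the vehicle mean for B4galnt4, Frmd6 and Tas2r110, and 5 of 6 for Nabp2, named next. From 3 to 24 h 401 features differed, 344 upward, led by C5ar1 (3.09, SE 0.36, adjusted p = 7.25e-08), Il1b (2.48, SE 0.36, adjusted p = 4.15e-06) and Serpinb1a (2.43, SE 0.59, adjusted p = 0.00922), while Cadps (-1.34), Nabp2 (-1.26, with animal 0766 far below the others at 3 h) and Cd36 (-0.97, SE 0.21, adjusted p = 0.00242) moved down. The inflammatory list differed from 3 to 24 h (6 of 36 members upward, 6 over the list alone; median 0.04, adjusted p = 0.00312, adjusted p = 0.0445 with an estimated correlation), as did the immediate early list (3 of 26 upward, 6 over the list alone; median 0.23, adjusted p = 0.00395, adjusted p = 0.0445 with an estimated correlation). The erythroid list moved the other way (1 of 27 downward, 6 over the list alone; median -0.16, adjusted p = 5.53e-05, adjusted p = 0.0445 with an estimated correlation). The ribosomal list differed only with the preset correlation (median 0.40, adjusted p = 2.66e-09, adjusted p = 0.24 with an estimated correlation).

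Most features lower at 1500 mg/kg at 3 and 6 h were also lower at 2000 mg/kg, while most features lower at 2000 mg/kg did not pass at 1500 mg/kg. Of the 182 features lower at 3 h after 1500 mg/kg 180 were also lower after 2000 mg/kg, where 15.1 would be shared by independent lists, and at 6 h 87 of 96 were shared (7.93 expected), out of 1221 and 1213 lower at 2000 mg/kg. Of the higher features 5 of 8 were shared at 3 h (0.073 expected) and 5 of 14 at 6 h (0.134 expected). At 24 h 56 higher (0.608 expected) and 35 lower features (0.177 expected) were shared, and no feature passed in opposite directions at 2 doses of a time. After 2000 mg/kg 679 features were lower at both 3 and 6 h (101 expected), and 23 passed in opposite directions at 3 and 24 h. Because both doses were set against the same 6 vehicle animals, part of any likeness is built in. Across features, which are not independent replicates, log2 differences at 1500 and 2000 mg/kg correlated at r = 0.871 (3 h), 0.839 (6 h) and 0.756 (24 h). Unchanged groups simulated against shared controls gave 0.498, 0.499 and 0.504, and splitting the vehicle animals between the doses gave 0.683, 0.607 and 0.31. The covariance was 0.0598, 0.0523 and 0.0286, where shared controls alone gave 0.0111, 0.0111 and 0.0113. For 150 and 2000 mg/kg r was 0.0662, 0.332 and 0.412, and -0.0791, 0.0991 and -0.0614 with split controls. Their covariance was 0.00298, 0.0139 and 0.0105, against 0.011, 0.0111 and 0.0111 simulated.

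Each animal was then assigned to a dose from the other 23 animals of its time by the nearest group mean over 100 features. At 3 h 16 of 24 animals were placed in their own dose (66.7%, exact 95% interval 44.7 to 84.4%), at 6 h 11 of 24 (45.8%, 25.6 to 67.2%) and at 24 h 4 of 24 (16.7%, 4.74 to 37.4%), where equal shares give 6 and relabelled animals gave medians of 5, 4 and 5. Placing animals only below or at and above 1500 mg/kg was right for 24 of 24 at 3 h (interval from 85.8%), 23 of 24 at 6 h (78.9 to 99.9%) and 22 of 24 at 24 h (73 to 99%), with medians of 12, 11 and 10 for relabelled animals. By dose (0, 150, 1500 and 2000 mg/kg), 5, 2, 5 and 4 of 6 animals were placed in their own dose at 3 h. These counts were 1, 3, 2 and 5 at 6 h and 1, 0, 0 and 3 at 24 h. At 6 h 5 of 6 vehicle animals were placed at 150 mg/kg. With 500 features 10 animals were placed in their own dose at 24 h, and with arrays of 1 dye orientation 7. With 1 minus the Pearson correlation as the distance 19, 20 and 21 of 24 animals were on the right side at 3, 6 and 24 h, and 13, 10 and 5 in their own dose, and relabelled animals were not run with that distance.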

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

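The tests of array design, dye, cell shares and single animals, and the relabellings of the assigned animals, were chosen after the results were seen. The splits of the animals for counts of features and lists were set before.

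Some animals lay far from the other 5 of their group. Of 255 groups examined (197 of a named gene and 58 of a list score), 24 had a gap to the nearest animal that, over the group's range, exceeded Dixon's critical value for 6. Chance gives at most 12.8, about 1 in 20, since groups with a missing value were counted but could not be tested. At 3 h these were vehicle animal 7558 for St8sia3 (gap over range 0.732), and at 2000 mg/kg animal 0766 for Gjb6 (0.652), Bpifa2f (0.79), Nabp2 (0.646) and the heat shock score (0.672), and animal 4010 for Madd (0.771), Serpinb1a (0.766), the monocyte score (0.657) and the neutrophil score (0.744). At 6 h they were vehicle animal 6034 for S100a10 (0.627) and the natural killer score (0.673), vehicle animal 7270 for the unfolded protein score (0.689), animal 4178 for Ankrd34b (0.716), animal 0621 for Sumo2 (0.724), animal 8066 for Cpne8 (0.793) and animal 2864 for the ribosomal score (0.631). At 24 h vehicle animal 7067 was high for Serpinb1a (0.836), S100a9 (0.651), Slpi (0.67), the inflammatory score (0.763) and the neutrophil score (0.636). Vehicle animal 8002 stood apart for Cir1 (0.632), vehicle animal 5480 for Frmd6 (0.796) and animal 5421 for Gda (0.673).

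The difference of 2000 mg/kg from vehicle changed with time in the fitted interaction. It differed for 1 feature between 6 and 3 h, for 538 between 24 and 6 h and for 401 between 24 and 3 h. By list, the immediate early genes differed between 6 and 3 h (median 0.0944) and between 24 and 3 h (0.23), and the erythroid (-0.16) and inflammatory genes (0.0395) between 24 and 3 h.

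At 2000 mg/kg 1221 features fell at 3 h and 1213 at 6 h, T and B cell markers and ribosomal protein genes among them. A difference between the 2 array designs as the whole cause is argued against: among animals of 1 design the median difference was 107.1% of that over all animals at 6 h, and 75.2% at 3 h, where only 2 vehicle animals remained. Of the genes that fell with the animal in Cy5, 99.6% (3 h) and 98.9% (6 h) were also lower with the animal in Cy3. This cannot decide on a dye effect, since each orientation compares animals in the same dye, where a common dye effect cancels. A lower share of all white blood cells alike would lower neutrophil and T cell markers together. At 6 h it is argued against as the whole cause, since the neutrophil list mean was not lower than in vehicle animals (difference 0.1). The neutrophil score there lay above the T cell score by 0.697, against 0.058 in vehicle animals (exact permutation p = 0.00216, two-sided). At 3 h the 2 scores differed by 0.375, against 0.034 (exact permutation p = 0.0216, two-sided). Both fell there, and lists may respond unequally to the same loss, so the difference cannot decide at 3 h. The neutrophil (-0.288 against -0.033 in vehicle animals), monocyte (-0.153 against -0.037) and natural killer scores (-0.212 against -0.015) were lower too at 3 h. A common decrease (in part, or at 3 h as a whole), a loss of lymphocytes from the blood and a lower transcript level per cell stay open as hypotheses. No cell counts are in the sources used here.

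At 24 h the neutrophil list rose. That 1 or 2 animals carry the rise is argued against, with 5 of 6 animals above the highest vehicle animal at 2000 mg/kg and 5 of 6 at 1500 mg/kg. The rise was uneven. At 1500 mg/kg 0861, 8385 and 6173 scored 1.24, 1.12 and 0.78 and the others 0.12 to 0.44. At 2000 mg/kg 1987 and 5402 scored 0.98 and 0.73 and the others 0.20 to 0.44. In 0861, 8385, 1987 and 5402 T cell scores were -0.82, -1.03, -0.64 and -0.86, and liver-secreted scores 0.34, 0.29, 0.30 and 0.26. In 2486 and 2342 T cell scores were 0.21 and 0.23. A lower share of red cell RNA raising all white blood cell lists alike is argued against as the whole cause. T cell means were not raised (-0.271 at 2000 and -0.352 at 1500 mg/kg, against -0.046 in vehicle animals). The neutrophil score rose over the T cell score within animals (exact permutation p = 0.0152 at 2000 and 0.00216 at 1500 mg/kg, two-sided). That difference alone cannot decide, since lists may respond unequally. Erythroid means were lower (-0.193 and -0.145, against -0.025). In 2486 and 2342 erythroid scores were -0.26 and -0.18, and neutrophil scores 0.44 and 0.27. A lower red cell share in part, an influx of neutrophils and activation of those present stay open as hypotheses.

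How often other groupings of the animals give as many changed features was counted over 100 splits of the same animals, the real one included, without adjustment over the comparisons. Over so many comparisons a count that 2, 3 or 4 splits reach does not exclude chance. A count that only the real split reaches is the smallest result possible and argues against chance for that comparison taken alone. At 3 h 1 split, the real one, was as large for 1500 mg/kg (190 features, highest other 2) and for 2000 mg/kg (1355, highest other 710). For 1500 against 150 mg/kg it was 2 splits (481, highest other 654). At 6 h 2 splits were as large for 1500 mg/kg (110, highest other 368) and 1 for 2000 mg/kg (1354, highest other 409). The count of 110 was unstable, with 0 features without animal 0426, 9676, 3273 or 6749. For 1500 against 150 mg/kg at 6 h (2 features) 4 splits were as large (highest other 75). Separate fits, either dye orientation alone and centring with scaling gave 0 there, while array weights gave 739. At 24 h 3 splits were as large for 1500 mg/kg (178, highest other 460) and 1 for 1500 against 150 mg/kg (152, highest other 81). For 2000 mg/kg 4 splits were as large (120, highest other 550), and a fit of the 24 h animals alone left 4 features there. The highest splits at 3 and 6 h for 1500 against 150 mg/kg (654 and 75) and at 6 h for 1500 mg/kg (368) exchanged only 1 animal of each group, so they kept most of the dose contrast. The highest at 24 h for 1500 and 2000 mg/kg (460 and 550) moved 4 of 12 animals and called several times the real count, which points to a structure of the samples, although what these splits share was not tested. For 150 mg/kg (0 features with limma, with 616, 693 and 399 at an unadjusted p under 0.05) all 100 splits were as large, with highest others of 3, 3 and 62, and for 2000 against 1500 mg/kg (0 features, with 549, 677 and 506) also 100, with highest others of 3, 622 and 3308, but a count of 0 makes every split as large, so this decides nothing. The splits with 622 and 3308 features, which moved 4 and 6 of 12 animals, far exceed the real count and also point to a structure of the samples.

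For the differences between times 1 split was as large between 24 and 6 h (538, highest other 23) and 3 between 24 and 3 h (401, highest other 1337). Between 6 and 3 h 5 splits were as large (1, highest other 580). These splits relabelled dose within each time and so removed the dose effect itself. They therefore cannot decide whether a change of the effect between times arose by chance. What the splits with high counts share was not tested. For the number of lists past camera the fewest splits were as large at 24 h after 2000 mg/kg (8 lists, 4 splits as large, highest other 10). Without adjustment over the comparisons this does not exclude chance, although 3 of the lists passed there with an estimated correlation. Chance cannot be excluded either at 3 h (3, 5 and 6 lists at 150, 1500 and 2000 mg/kg, with 30, 9 and 14 splits as large and highest others of 10, 7 and 9), at 6 h (1, 4 and 4 lists, with 44, 23 and 13 splits and highest others of 6, 6 and 7) or at 24 h for 1500 mg/kg (5 lists, 38 splits, highest other 11). For 150 mg/kg at 24 h (0 lists, 100 splits, highest other 5) the count of 0 decides nothing. For the assignment of animals to their own dose, over 101 labellings, 1 labelling was as good at 3 h (16 right, highest other 12). It was 2 labellings at 6 h (11 right, highest other 11) and 65 at 24 h (4 right, highest other 12), where chance cannot be excluded. Relabelling also removed the split at 1500 mg/kg. At 3 and 6 h it therefore cannot tell recognition of an animal's own dose from recognition of its side of 1500 mg/kg. For the side of 1500 mg/kg 1 labelling, the real one, was as good at each time, which argues against chance there. The counts were 24 at 3 h (highest other 19), 23 at 6 h (highest other 20) and 22 at 24 h (highest other 19).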

How the results depend on the processing

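The settings with exact zeros kept, with 1 array sufficing, with the array design and without animals apart within their group were chosen after seeing the data, as were the split of controls for 150 and 2000 mg/kg and the list means with each animal left out. Unless a reason is given the cause was not tested. Of 2048 values of named genes over 8 settings 1699 stayed past the threshold with the same sign, 349 kept the sign without passing, and 0 took the other sign. These genes were chosen for passing in the same animals, so the absence of sign changes says little.

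Leaving out 1 animal in turn gave 10 to 248 features for 1500 mg/kg at 3 h, 872 to 1411 for 2000 mg/kg at 3 h, 0 to 993 for 1500 mg/kg at 6 h, 921 to 1617 for 2000 mg/kg at 6 h, 101 to 272 for 1500 mg/kg at 24 h and 71 to 170 for 2000 mg/kg at 24 h; the counts for 150 mg/kg stayed at 0. Without any 1 vehicle animal the count for 1500 mg/kg at 6 h was 48 or lower. It was 6 or lower without treated animal 0089, 0426, 4178 or 9676, and 993 without treated animal 0621. The count is therefore unstable to the loss of most animals, rather than carried by a few of them.

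Array weights gave 1214, 1820 and 90 features for 1500 mg/kg at 3, 6 and 24 h, 3917, 3466 and 60 for 2000 mg/kg, 1109 (3 h) and 739 (6 h) for 1500 against 150 mg/kg, 614 and 614 for 2000 against 1500 mg/kg at 3 and 6 h, 8 for 150 mg/kg at 6 h, and 60, 1454 and 1742 for the differences between times. Against the pool, which drops the spread of the vehicle animals, the counts were 8, 28 and 104 (150 mg/kg), 2513, 1968 and 726 (1500 mg/kg) and 4588, 5655 and 1399 (2000 mg/kg).

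Single arrays with the animal as a random block gave 651, 545 and 279 for 1500 mg/kg, 877, 263 and 280 for 1500 against 150 mg/kg, 236 for 2000 mg/kg at 24 h, 3 for 2000 against 1500 mg/kg at 3 h, 10 between 6 and 3 h and 725 between 24 and 3 h. Separate fits per time gave 488, 227 and 40 for 1500 mg/kg, 766, 0 and 28 for 1500 against 150 mg/kg, and 4 for 2000 mg/kg at 24 h.

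With only arrays with the animal in Cy5 the counts were 46, 8 and 102 for 1500 mg/kg, 862 and 66 for 2000 mg/kg at 3 and 24 h, 212, 0 and 101 for 1500 against 150 mg/kg, and 0, 233 and 208 between times, and 7 animals were assigned to their own dose at 24 h. With only arrays with the animal in Cy3 they were 107 and 5 for 1500 mg/kg at 3 and 6 h, 900 and 720 for 2000 mg/kg at 3 and 6 h, 0 for 1500 against 150 mg/kg at 6 h, 0 and 224 for 6 against 3 h and 24 against 6 h, 0 lists for 150 mg/kg at 6 h, and 7 animals at 24 h. Fewer arrays were used in both.

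A minimum of 1.5-fold, which can only lower a count, gave 861 and 738 for 2000 mg/kg at 3 and 6 h, 67 at 24 h, 72 and 99 for 1500 mg/kg at 6 and 24 h, 84 for 1500 against 150 mg/kg at 24 h and 346 between 24 and 6 h. Centring and scaling gave 287 and 0 for 1500 against 150 mg/kg at 3 and 6 h, 21 for 1500 mg/kg at 6 h, 354 between 24 and 6 h and 0 between 6 and 3 h. For the last comparison, 1 feature in all animals, centring, robust empirical Bayes, exact zeros kept, 1 array sufficing and 2 animals per group also gave 0, and single probes gave 2.

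Exact zeros kept gave 43 and 1 array sufficing 68 for 1500 mg/kg at 6 h. The array design as a covariate gave 297 for 1500 mg/kg at 3 h. Within 1 design, with fewer animals, 2 features passed for 150 mg/kg, 1 for 1500 mg/kg and 1 for 2000 mg/kg at 3 h, and 3 for 150 mg/kg and 766 for 1500 mg/kg at 6 h. The last count also leaves out animal 0621. Without the 9 animals apart within their group the counts were 744, 1126 and 106 for 1500 mg/kg, 67 for 2000 mg/kg at 24 h, 712 and 95 for 1500 against 150 mg/kg at 6 and 24 h, 1 and 1 for 2000 against 1500 mg/kg at 3 and 24 h, and 2 between 6 and 3 h.

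With an estimated correlation 0 lists passed for 150, 1500 and 2000 mg/kg at 3 h and 0 at 6 h, and 3 passed at 24 h for 1500 mg/kg and 3 for 2000 mg/kg. With the probe of largest variance 2 lists passed for 150 mg/kg at 6 h. With 500 genes 10 animals were assigned to their own dose at 24 h. With the controls split the correlation of 150 and 2000 mg/kg turned to -0.0791 at 3 h and -0.0614 at 24 h, since the shared vehicle animals were removed. Signal over background is not in the sources used here, so what it limits is not known.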

Other observations

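The components of the differences within groups were computed after the other results were seen. The first 2 held 20.1% and 10% of the variance within groups. At 1 end of the first lay Rbbp7, RT1-Da, Acp5, Bin1, Coro1a and Spib, and at the other Ccl2, S100a8, Rdh7, Cntn2, Cox7b and Padi1, so that genes that fell with dose also varied among animals of 1 dose. 9 animals lay over 2 SD from the centre on either component. Of 5 markers of glucocorticoid, metal or oxidative exposure looked at singly, Fkbp5 rose at 3 h after 2000 mg/kg (0.39, adjusted p = 0.0122 with limma), Mt1 fell at 6 h after 2000 mg/kg (-0.49, adjusted p = 0.00547), and Mt2A, Hmox1 and Tsc22d3 passed in no comparison of a dose with vehicle. Other members of the glucocorticoid list passed. Il6r was lower at 3 h after 2000 mg/kg (-0.84), Dusp1 was higher at 6 h after 1500 mg/kg (0.28), Pdk4 (0.30) and Dusp1 (0.27) at 6 h after 2000 mg/kg, and Cebpd (1.08), Sgk1 (0.79) and Dusp1 (0.29) at 24 h after 1500 mg/kg, each in 6 of 6 animals. The list as a whole passed camera at no dose and time.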
